A study of Homo sapiens with 15 samples.

How the data were processed

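RNA was sequenced from 15 libraries of human cultures, in 5 groups of 3 given by the sample titles. RPTEC/TERT1 cells, an immortalized line of renal proximal tubular epithelium, grew on LN/FN-silk membranes, made with recombinant spider silk, or on LN/PC membranes. On each membrane they grew alone or together with fHDF/TERT166 cells, an immortalized line of human dermal fibroblasts, and the fifth group held fibroblasts alone. Epithelial cells were seeded at 140000 and fibroblasts at 14000 cells per cm2, and cultures were collected 14 days after seeding, per the labels' protocols. Silk membranes were scraped off and LN/PC membranes were cut from their holder, so the way of harvest differed with the membrane. Fibroblasts came from the bottom of the well. The protocol calls these fibroblasts basolateral while the titles call them monocultures, and they are treated here as monocultures. Each sample pooled 3 to 8 membranes. Libraries were made from poly-A selected RNA with a strand-keeping kit and sequenced on a NovaSeqX plus instrument, per the labels' protocols. The labels do not say that replicates were separate cultures, so the p-values given here measure the spread between these samples, which may be partly technical.

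Reads were quantified with Salmon 1.10.3 and handled with DESeq2, per the submitters' processing notes. The genome build, the annotation and the DESeq2 settings are not given in the sources used here. The deposited table, called normalized counts by the authors, holds 15790 genes in 15 columns, each matching 1 sample title. Its values are not on a count scale: the deposited values are on a log2 scale with a floor of 5.53664461 in every library, the form that a variance-stabilizing transformation gives. They were turned back to normalized counts by inverting that transformation with the floor as its single constant. As a check, the median ratio of each library to the per-gene geometric mean was computed over the 13121 genes above the floor in all libraries. It was 1.01175 in each library with a spread of 6.27e-09, against 0.994 to 1.002 for 2 raised to the deposited value. A value at the floor becomes 0. The planned design had foreseen normalized values on a linear scale, so this step was added after the table was seen. A test of the deposited log2 values as they stand was added as an alternative.

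Totals ran from 9.08 to 12.7 per library, in units of 1e6 normalized counts. The spacing of low values put 1 read at 0.755 to 1.23 normalized counts and the assigned reads at about 8.80 to 14.7 per library in the same units of 1e6. Whole reads were not recovered, since 36.2% to 59.5% of low values lay within 0.1 of a whole read, so no count model was fitted. PCR reads carry no molecular identifiers, so floors cover counting error only. A gene at 0 in all libraries of a group was given a floor of 3 reads per library, and its fold change is a lower bound. For a gene with 1 to 3 reads over a whole group, the ratio is given with a 95% conditional exact (Clopper-Pearson) interval of the rounded reads. These intervals pool the approximate reads of a group. They cover counting error only and leave out the spread between libraries.

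Each comparison used limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), with Benjamini-Hochberg adjustment over the tested genes and a call at an adjusted p under 0.05. Log2 fold changes on this scale understate the change of low genes. Genes with a value of at least 10 in at least 3 libraries of the fit were tested. The 4 epithelial groups entered 1 fit of 12 libraries and 14433 genes, which gave 4 pairwise comparisons, the membrane by co-culture interaction and the membrane effect averaged over culture type. Fibroblasts were compared with the epithelial monocultures in a fit of 9 libraries. The share of fibroblast RNA in a co-culture was the median over 112 marker genes of the library's excess over the monocultures of its membrane, as a percent of the excess in fibroblasts. Markers had a mean of at least 1000 in fibroblasts and at least 100 times that of each epithelial monoculture, and were chosen without the co-cultures. Each co-culture group was also compared with 3 in-silico mixtures of monoculture and fibroblast libraries at its mean share.

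For 39 gene lists, camera (correlation 0.01) compared the members with the other genes of the same fit, with Benjamini-Hochberg adjustment over the 37 lists that had at least 3 measured members. Calls were recomputed with an estimated correlation and with fry. Members called over all genes and members called when adjusted over the list alone were counted. The genes named in the text follow a rule. In each pairwise comparison they are the 5 largest log2 changes per direction among called genes with a mean of at least 100 in the higher group and no overlap between the groups' libraries, up to 4 called members of each list, and a fixed panel of tubular genes. In the other comparisons they are the 4 largest per direction. The text gives fewer where lists overlap, and a few genes that the rule picks are not reported. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. LRP2, HNF4A, SLC22A6 and SLC34A1 of the panel are not analysed here. Genes whose reads may be shared with near-identical copies are reported with that limit.

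The tests were checked on simulated data built from these libraries. For the comparison of silk and LN/PC monocultures (14272 genes), 8.96% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 90.9% of those changed 4-fold were called, 100% of them in the right direction. Of the simulated calls, 11.4% were unchanged genes, which is above the nominal rate. With no change simulated (14240 genes), 0 genes and 0 lists were called. Genes were simulated independently of each other, so the 0 lists do not show how camera behaves with genes that vary together. For the LN/PC co-cultures, a simulated fibroblast share of 15% was estimated at 15.1% (15790 genes), and a true mixture gave 0 calls (14476 genes). That mixture had the same dispersion for all genes and the same fibroblast profile as its reference, so it does not cover fibroblasts that change in co-culture.

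The alternatives were other pseudocounts (0.1 and 10), no filter or a filter at 100, trimmed-mean and upper-quartile scaling, voom weights, robust variance moderation, fits of the compared groups or of all 15 libraries, the replicate number as a block, each library left out in turn, a log2 fold threshold of 1, other marker sets and other mixture shares. A rescaling on 552 epithelium-restricted genes, with a fibroblast mean under 5% of the epithelial mean, and a mixture at the summed marker share were added after the data were seen. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.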

Results

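Gene expression was measured in 15 cultures: epithelial monocultures and epithelial and fibroblast co-cultures on silk, the same on LN/PC, and fibroblast monocultures, with 3 libraries in each group. Totals of normalized counts, in units of 1e6, averaged 9.26 ± 0.0641 (SD, n = 3) in silk monocultures, 10.2 ± 0.131 in silk co-cultures, 10.0 ± 0.906 in LN/PC monocultures, 11.2 ± 0.695 in LN/PC co-cultures and 12.5 ± 0.241 in fibroblast monocultures. In a principal component analysis of the 12 epithelial libraries, the first component (51.1% of the variance) set the 3 LN/PC co-culture libraries (92.8 to 110) apart from the other 9 (-51.9 to -7.63). The second (18.8%) placed the LN/PC monoculture libraries lowest, and LN/PC monoculture 2 (-30.6) lay nearer to the silk libraries than LN/PC monoculture 1 (-56.6) and LN/PC monoculture 3 (-76.6). Mitochondrially encoded transcripts took 5.157 ± 1.248% of the counts in silk monocultures, 5.97 ± 0.501% in silk co-cultures, 2.48 ± 1.19% in LN/PC monocultures, 2.37 ± 0.584% in LN/PC co-cultures and 1.99 ± 0.329% in fibroblast monocultures.

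The fibroblast libraries were compared with the epithelial monocultures to give a profile of each cell type. The fibroblasts expressed interstitial collagen genes at high level, with 109350 ± 8330 normalized counts of COL3A1 (SD, n = 3), 122160 ± 12502 of COL1A2 and 90161 ± 2805 of COL6A3. COL3A1 was at 0 in all 6 epithelial monocultures, so it was at least 38674-fold higher in fibroblasts, and the alcohol dehydrogenase gene ADH1B at least 10359-fold higher. COL1A2 and COL6A3 were higher by 16.11 ± 0.84 and 15.30 ± 0.67 log2 units (SE). The epithelial cells expressed SPP1 (osteopontin), at 116280 ± 13054 in silk monocultures and 141270 ± 39728 in LN/PC monocultures, SERPINA1 (alpha-1-antitrypsin) and FXYD2, a subunit of the sodium pump. All 3 were at 0 in every fibroblast library and at least 42572-fold, 8309-fold and 3967-fold lower there. CD24, with about 2 reads over the 3 fibroblast libraries, was 61210-fold lower (95% exact interval 16944 to 5.05e+05). Of 33 fibroblast markers measured, 32 were higher and 1 lower in fibroblasts (median log2 9.97, or 9.29 with genes at 0 set to their bound), and 28 of 32 tight junction and polarity genes were lower (median -6.10, or -5.23 at the bound). Of 36 ribosomal protein genes, 31 were higher (median 0.77). By limma with Benjamini-Hochberg adjustment, 8460 of 14502 genes were called, 4061 higher and 4399 lower in fibroblasts. By camera, 20 of 37 lists were called, with fibroblast markers (adjusted p = 4.12e-19) also called with an estimated correlation (adjusted p = 0.00422). Tight junction (adjusted p = 0.0777 with an estimated correlation) and ribosomal protein genes (adjusted p = 0.503 with an estimated correlation) were not.

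How much fibroblast RNA the co-cultures held was estimated from 112 fibroblast-restricted genes. Fibroblast RNA made up 13.9%, 9.81% and 15.2% of the 3 LN/PC co-culture libraries (mean 13.0 ± 2.80%, SD, n = 3) and 0.0239%, 0% and 0.113% of the 3 silk co-culture libraries (mean 0.0457 ± 0.0597%). All 3 LN/PC co-cultures values lay above all 3 silk co-cultures values (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The SD covers the spread between libraries only. Between markers the shares were wide, with quartiles of 6.67% and 22.7%, 4.32% and 15.1%, and 9.23% and 26.1% in LN/PC co-cultures 1 to 3. Summed over the markers, expression reached 20.997 ± 5.81% of the fibroblast level in LN/PC co-cultures and 0.273 ± 0.0566% in silk co-cultures, against 0.147 ± 0.00689% in LN/PC monocultures and 0.155 ± 0.00497% in silk monocultures. The share taken from the summed markers was 20.9 ± 5.81% in LN/PC co-cultures and 0.118 ± 0.0567% in silk co-cultures, and without silk co-culture 3 the mean share of the silk co-cultures was 0.0119%. The summed markers of silk co-cultures, from 0.229% to 0.337%, lay above the silk monoculture libraries. Fibroblasts were 9.09% of the cells seeded in both kinds of co-culture. COL1A1, the collagen type I alpha 1 gene, averaged 35573 ± 7231 normalized counts in LN/PC co-cultures and 120 ± 87.0 in silk co-cultures, against 109270 ± 10487 in fibroblast monocultures. The gap in fibroblast RNA runs alongside each comparison of silk co-cultures with LN/PC co-cultures and of LN/PC co-cultures with LN/PC monocultures given here.

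**Figure D1:**
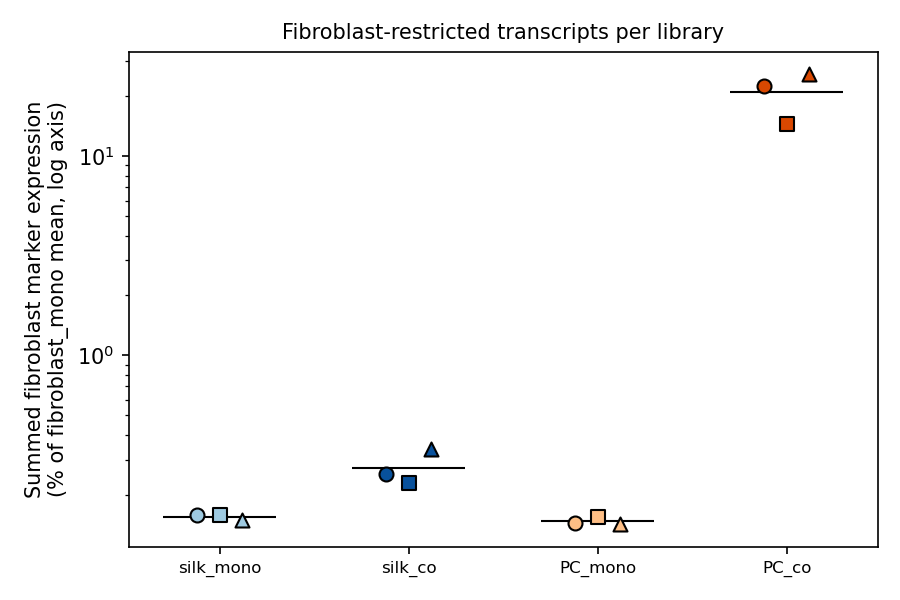
Summed expression of 112 fibroblast-restricted genes in each of 12 libraries, as a percent of the mean of the fibroblast monocultures, on a log axis, with 1 symbol per replicate and a line at the group mean. The LN/PC co-culture libraries lie between 14.6% and 25.9%, and the silk co-culture libraries between 0.229% and 0.337%.

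Silk and LN/PC monocultures were compared to ask how the epithelial cells differed with the membrane in the absence of fibroblasts. In each comparison of silk with LN/PC the way of harvest differed too, so membrane and harvest cannot be told apart for any gene or list. On silk the proximal tubule anion transporter genes SLC17A1 and SLC17A3 were higher by 3.91 ± 0.83 and 2.61 ± 0.33 log2 units (SE, n = 3 per group), at 105 ± 13.5 and 416 ± 114 normalized counts (SD) against 12.7 ± 13.4 and 71.8 ± 39.9. NPR3, the natriuretic peptide clearance receptor gene, was higher by 3.62 ± 0.37 and the glycosyltransferase gene GCNT3 by 3.02 ± 0.41. Genes of secreted proteins were among those lower on silk: A2M (alpha-2-macroglobulin) was at 3.68 ± 2.83 on silk and 582 ± 307 on LN/PC (log2 -7.11 ± 0.68), RELN (reelin) at 13.0 ± 3.43 and 572 ± 110 (-5.36 ± 0.41) and COL21A1 at 6.57 ± 3.59 and 284 ± 113 (-5.26 ± 0.51). HP (haptoglobin), with about 2 reads over the silk libraries, was 200-fold lower there (95% exact interval 55.1 to 1660). Reads of HP may be shared with HPR, so this value is uncertain.

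Interferon response genes had the lowest camera p value between the monocultures. Of 35 measured, 20 were lower and 0 higher on silk (28 lower when adjusted over the list alone), with a median of -0.87. For interferon response, camera gave adjusted p = 5.82e-16 (adjusted p = 0.541 with an estimated correlation). Among them IFI6 averaged 237 ± 15.7 on silk and 1576 ± 710 on LN/PC (-2.62 ± 0.28), and OAS2 (-4.27 ± 0.46), IFI27 (-3.14 ± 0.68) and OASL (-2.95 ± 0.80) were also lower. Of 28 inflammatory and NF-kB genes, 5 were lower and 0 higher (9 lower and 2 higher over the list alone), including IL33 (-4.53 ± 0.54), TNFAIP3 (-2.00 ± 0.51) and RELB (-1.61 ± 0.39), with a median of -0.57. For inflammatory cytokines and NF-kB, camera gave adjusted p = 0.00209 (adjusted p = 0.783 with an estimated correlation). The mean of this list, relative to the LN/PC monocultures, was -0.77, -0.41 and -0.77 in the silk monocultures and 0.27, -1.16 and 0.89 in LN/PC monocultures 1 to 3, so LN/PC monoculture 2 lay below every silk monoculture. Immediate early genes had 6 of 22 lower and 0 higher (10 lower over the list alone), among them EGR3 (-3.91 ± 0.70), EGR2 (-3.29 ± 0.51), FOS (-3.00 ± 0.52) and EGR1 (-1.78 ± 0.50), with a median of -0.51. For immediate early genes, camera gave adjusted p = 0.000828 (adjusted p = 0.717 with an estimated correlation). The unfolded protein response list had 5 of 25 lower and 0 higher (8 lower over the list alone, median -0.20), including the serine synthesis gene PHGDH (-1.31 ± 0.31) and the chaperone gene HSPA5 (-0.90 ± 0.22). For unfolded protein response, camera gave adjusted p = 0.0249 (adjusted p = 0.717 with an estimated correlation). Replication-dependent histones had 1 of 8 lower (1 over the list alone, median -0.68). For replication-dependent histones, camera gave adjusted p = 0.036 (adjusted p = 0.717 with an estimated correlation).

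Cholesterol synthesis genes moved the other way, with 8 of 24 higher and 0 lower on silk (16 higher over the list alone) and a median of 0.51. For cholesterol synthesis, camera gave adjusted p = 7.20e-07 (adjusted p = 0.673 with an estimated correlation). HMGCS1 averaged 1948 ± 287 on silk and 842 ± 164 on LN/PC (1.22 ± 0.20), and SQLE (1.01 ± 0.17), SC5D (0.94 ± 0.18) and MSMO1 (0.88 ± 0.13) were higher with it. Mitochondrially encoded transcripts had 7 of 13 higher (12 over the list alone, median 0.90), with MT-CO1 (1.18 ± 0.37) and MT-CO2 (1.11 ± 0.28) among them. For mitochondrially encoded transcripts, camera gave adjusted p = 1.92e-05 (adjusted p = 0.717 with an estimated correlation). Of 23 YAP and TEAD targets, 7 were higher and 0 lower (13 higher over the list alone), including NUAK2 (1.51 ± 0.28), FJX1 (1.13 ± 0.28) and AJUBA (1.11 ± 0.21), with a median of 0.46. For YAP and TEAD targets, camera gave adjusted p = 8.14e-05 (adjusted p = 0.541 with an estimated correlation). Cell proliferation genes had 8 of 37 higher and 0 lower (10 over the list alone), with E2F1 (1.20 ± 0.33), CCNA2 (1.16 ± 0.28) and CDC6 (1.13 ± 0.31) and a median of 0.44. For cell proliferation, camera gave adjusted p = 8.14e-05 (adjusted p = 0.738 with an estimated correlation). The hypoxia response list had 9 of 25 higher and 1 lower (the same numbers over the list alone, median 0.30), including the carbonic anhydrase genes CA9 (3.38 ± 0.91) and CA12 (2.07 ± 0.26) and ANGPTL4 (2.52 ± 0.39). For hypoxia response, camera gave adjusted p = 0.0249 (adjusted p = 0.717 with an estimated correlation). NRF2 and heme stress genes had 3 of 18 higher (4 higher and 1 lower over the list alone, median 0.48). For NRF2 and heme stress, camera gave adjusted p = 0.0193 (adjusted p = 0.717 with an estimated correlation). Metallothioneins, whose MT1 members may share reads, had 1 of 6 higher (4 over the list alone, median 0.64). For metallothioneins, camera gave adjusted p = 0.0257 (adjusted p = 0.717 with an estimated correlation).

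Tubular genes went both ways in the monocultures. Of 20 measured proximal tubule transporters, 5 were higher and 1 lower on silk (median 0.08, camera adjusted p = 0.275). Many other members of that list, among them SLC22A2, SLC22A8, SLC47A1, SLC5A2, ABCC2 and ABCG2, are not analysed here. ABCB1, the P-glycoprotein gene, averaged 1351 ± 51.2 on silk and 1122 ± 460 on LN/PC, CUBN (cubilin) 61.9 ± 42.1 and 41.0 ± 21.7, AQP1 10.7 ± 3.94 and 10.3 ± 4.38 and COL1A1 24.9 ± 14.7 and 21.2 ± 18.5, none of them called. The cadherin genes CDH6 (1.38 ± 0.21) and CDH1 (1.15 ± 0.27) and the claudin gene CLDN16 (1.45 ± 0.19) were higher among 32 tight junction and polarity genes (7 higher, 2 lower, median -0.07, camera adjusted p = 0.847). HAVCR1, which encodes the tubular injury marker KIM-1, was higher on silk (332 ± 70.0 against 138 ± 97.3, log2 1.69 ± 0.52, limma adjusted p = 0.0462) within an injury list that had 7 higher and 4 lower of 34. GREM1 (2.03 ± 0.41) was higher on silk at low level, and PDGFRB, with about 3 reads over the LN/PC monoculture libraries, was 11.8-fold higher (95% exact interval 3.72 to 59.7), while the fibroblast list had 4 higher and 4 lower of 32.

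By limma, 1685 of 14433 genes were called between the monocultures, 849 higher and 836 lower on silk, of which 469 and 301 by at least 2-fold. With the 6 compared libraries alone in the fit the count was 754, 392 higher and 362 lower. With library totals rescaled to the upper quartile 60.5% of the calls were higher on silk, and with rescaling on epithelium-restricted genes 34.1%, against 50.4%. By camera 12 of 37 lists were called, and 0 with an estimated correlation, where the lowest adjusted p was 0.541, and fry called 3. Left out singly, LN/PC monoculture 2 raised the number of called genes to 3208, while LN/PC monoculture 1 (1064), LN/PC monoculture 3 (695), silk monoculture 1 (881), silk monoculture 2 (1041) and silk monoculture 3 (1039) lowered it. Leaving out 1 library of the silk monocultures, LN/PC monocultures or silk co-cultures ended the calls of OASL, IFI27, TNFAIP3, RELB, EGR1, PHGDH, HSPA5, MT-CO1, MT-CO2, E2F1, CCNA2, CDC6, CA9, HAVCR1, FJX1 and CDH1, at limma adjusted p values up to 0.175. HAVCR1 was at 26.9 in LN/PC monoculture 2, against 209 and 178 in the others of that group. Without that library its log2 difference was 0.76 and that of EGR1 -1.16, without LN/PC monoculture 1 that of CA9 was 1.77, and without LN/PC monoculture 3 that of SLC17A1 was 2.50.

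Some list calls between the monocultures ended when 1 library was left out, which also leaves fewer samples, with camera adjusted p over 0.05. Without silk monoculture 1 this held for NRF2 and heme stress (adjusted p = 0.107). Without silk monoculture 2 it held for the unfolded protein response (0.0853), metallothioneins (0.0585) and histones (0.0853), and without silk monoculture 3 for hypoxia response (0.132), the unfolded protein response (0.158) and histones (0.0614). Without LN/PC monoculture 1 it held for hypoxia response (0.193) and metallothioneins (0.0872), and without LN/PC monoculture 2 for cell proliferation (0.104), NRF2 and heme stress (0.173) and histones (0.437). Without LN/PC monoculture 3 it held for inflammatory genes (0.183), the unfolded protein response (0.0798) and metallothioneins (0.0668). Where the call ended, the median fell to 0.07 for hypoxia response (without LN/PC monoculture 1), 0.24 for NRF2 and heme stress (without silk monoculture 1), -0.43 and -0.38 for histones (without silk monoculture 2 and LN/PC monoculture 2) and -0.29 for inflammatory genes (without LN/PC monoculture 3). For the unfolded protein response it fell to -0.13 and -0.08 (without silk monoculture 3 and LN/PC monoculture 3), and for metallothioneins it was 0.48 to 0.66. By list mean, single libraries of the 2 groups overlapped for cell proliferation, NRF2 and heme stress, metallothioneins, the unfolded protein response, inflammatory genes, mitochondrially encoded transcripts and histones.

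Silk and LN/PC co-cultures, whose harvest again differed with the membrane, were compared to ask how the membrane mattered with fibroblasts present. Fibroblast genes were among those lower on silk, alongside the fibroblast RNA of 0.0457% in silk co-cultures and 13.0% in LN/PC co-cultures. COL3A1 had a log2 difference of -11.07 ± 0.96 (SE, n = 3 per group), with 27.9 ± 24.3 normalized counts (SD) on silk and 27660 ± 10801 on LN/PC, and COL6A3 (-9.85 ± 1.097), LUM (-9.47 ± 0.66), COL1A2 (-9.24 ± 1.12) and COL1A1 (-8.61 ± 0.91) were lower too. POSTN, at 0 in all silk co-culture libraries and 1182 ± 475 in LN/PC co-cultures, was at least 403-fold lower. Of 32 fibroblast markers 29 were lower and 1 higher (the same over the list alone), with a median of -6.73, or -6.34 with genes at 0 set to their bound. For fibroblast markers, camera gave adjusted p = 6.70e-26 (adjusted p = 0.0624 with an estimated correlation). Myofibroblast and contractile genes had 13 of 17 lower and 1 higher (the same over the list alone, median -1.67), with MYL9 (-6.37 ± 0.69) and TAGLN (-5.96 ± 0.49). For myofibroblast and contractile genes, camera gave adjusted p = 8.00e-08 (adjusted p = 0.202 with an estimated correlation). Metalloproteinases and inhibitors had 11 of 22 lower and 3 higher (11 and 4 over the list alone, median -1.12, camera adjusted p = 0.00832, adjusted p = 0.263 with an estimated correlation), and TGF-beta response genes 12 of 26 lower and 5 higher (13 and 7 over the list alone, median -0.47). For TGF-beta response, camera gave adjusted p = 0.0214 (adjusted p = 0.214 with an estimated correlation).

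HSPA6, an inducible heat shock protein gene whose reads may be shared with HSPA7, averaged 488 ± 399 in silk co-cultures against about 3 reads over the LN/PC co-culture libraries, a 442-fold difference (95% exact interval 151 to 2145). That interval leaves out the spread between the silk co-culture libraries, which stood at 385, 929 and 151. UGT1A6, a glucuronosyltransferase gene that shares exons with its family and is uncertain for that reason, was higher by 4.21 ± 0.31, SH2D5 by 4.07 ± 0.42, the Wnt receptor gene FZD10 by 4.02 ± 0.38 and GAD1 by 3.82 ± 0.42. Of 18 NRF2 and heme stress genes, 13 were higher and 0 lower (the same over the list alone), including HMOX1 (716 ± 159 against 116 ± 32.5, 2.63 ± 0.33), OSGIN1 (2.35 ± 0.63) and FTL (1.68 ± 0.32), with a median of 0.78. For NRF2 and heme stress, camera gave adjusted p = 4.64e-05 (adjusted p = 0.263 with an estimated correlation). The 552 epithelium-restricted genes had a median of 0.43 in this comparison, so positive list medians of about that size need not reflect those lists. Cholesterol synthesis genes had 11 of 24 higher and 1 lower (13 and 1 over the list alone, median 0.54), with INSIG1 (1.72 ± 0.23) and HMGCS1 (1.23 ± 0.20). For cholesterol synthesis, camera gave adjusted p = 0.00308 (adjusted p = 0.591 with an estimated correlation). YAP and TEAD targets had 11 of 23 higher and 3 lower (12 and 3 over the list alone, median 0.66), with AJUBA (2.01 ± 0.21) and ANKRD1 (1.98 ± 0.59). For YAP and TEAD targets, camera gave adjusted p = 0.00525 (adjusted p = 0.437 with an estimated correlation). Mitochondrially encoded transcripts had 12 of 13 higher (12 over the list alone, median 1.09), with MT-ND1 (1.55 ± 0.31) and MT-CO1 (1.49 ± 0.37). For mitochondrially encoded transcripts, camera gave adjusted p = 0.000332 (adjusted p = 0.591 with an estimated correlation).

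The tight junction list had 14 of 32 higher and 3 lower in silk co-cultures (the same over the list alone), including CLDN16 (2.59 ± 0.19) and CLDN1 (2.38 ± 0.27), with a median of 0.38 that became -0.06 when rescaled on epithelium-restricted genes. For tight junction and polarity, camera gave adjusted p = 0.00113 (adjusted p = 0.394 with an estimated correlation). Glycolysis genes had 6 of 22 higher and 1 lower (the same over the list alone, median 0.31, or -0.14 so rescaled). For glycolysis, camera gave adjusted p = 0.0271 (adjusted p = 0.62 with an estimated correlation). Growth factor targets had 9 of 24 higher and 3 lower (the same over the list alone, median 0.16, or -0.29 so rescaled). For growth factor signalling targets, camera gave adjusted p = 0.0401 (adjusted p = 0.488 with an estimated correlation), and single libraries of the 2 groups overlapped by list mean. HAVCR1 was higher by 2.18 ± 0.52 (269 ± 10.5 against 61.0 ± 22.8), AQP1, which fibroblasts expressed at 6709 ± 448, was lower (-3.22 ± 0.55), and ABCB1 (891 ± 183 against 754 ± 106) and CUBN (36.3 ± 19.02 against 25.2 ± 23.9) were not called. Of 35 interferon response genes 18 were lower and 1 higher (19 and 1 over the list alone), among them OAS2 (-2.55 ± 0.46), XAF1 (-2.51 ± 0.31) and MX2, which was 24.0-fold lower (95% exact interval 7.86 to 120) with about 3 reads over the silk co-culture libraries. Their median was -0.73. For interferon response, camera gave adjusted p = 0.000292 (adjusted p = 0.591 with an estimated correlation). Immediate early genes had 11 of 22 lower and 1 higher (the same over the list alone, median -0.77), with FOSB (-5.25 ± 0.97) and EGR3 (-4.96 ± 0.70). For immediate early genes, camera gave adjusted p = 0.00257 (adjusted p = 0.591 with an estimated correlation). Primary cilium genes had 19 of 36 lower and 1 higher (21 and 1 over the list alone, median -0.54), including IFT20 (-1.43 ± 0.18). For primary cilium, camera gave adjusted p = 0.000113 (adjusted p = 0.292 with an estimated correlation). Ribosomal protein genes, which fibroblasts expressed more highly, had 20 of 36 lower and 0 higher (20 over the list alone, median -0.53), with RPS29 (-1.15 ± 0.22) and RPS24 (-0.94 ± 0.20). For ribosomal proteins, camera gave adjusted p = 4.64e-05 (adjusted p = 0.591 with an estimated correlation).

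By limma, 5214 of 14433 genes were called between the co-cultures, 2675 higher and 2539 lower on silk, of which 1274 and 1232 by at least 2-fold. Of the genes lower on silk, 628 were among the 1227 genes enriched in fibroblasts. Rescaling on epithelium-restricted genes moved the median of all genes by -0.44 and left 15.03% of the calls higher on silk, against 51.3%. By camera 15 of 37 lists were called, and 0 with an estimated correlation. Without LN/PC co-culture 1 the number of called genes was 3415, and ANKRD1 was not called without LN/PC co-culture 1, LN/PC co-culture 2 or LN/PC co-culture 3 (adjusted p up to 0.115). The glycolysis list (adjusted p = 0.169) and the metalloproteinase list (adjusted p = 0.0609) were not called without LN/PC co-culture 3, and the metalloproteinase median of -1.12 became -0.73, -0.15 and -0.48 without LN/PC co-culture 1, 2 and 3.

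Between the co-culture and monoculture comparisons, the membrane effects on all 14433 genes had a Pearson correlation of 0.378 and a Spearman correlation of 0.503 across genes, which are not independent replicates. The comparisons share no library, but they come from 1 fit with the same variance for each gene and carry the same difference of harvest. The agreement therefore does not single out the membrane, and independent lists are only a rough expectation. Of the genes called, 524 were higher on silk in both (157 by independent lists) and 467 lower in both (147 by independent lists), while 39 were higher in monoculture and lower in co-culture and 16 the reverse. Without the fibroblast-enriched genes the correlations were 0.586 and 0.558.

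Averaged over mono- and co-culture, GCNT3 (3.20 ± 0.29 log2 units, SE, 6 libraries per membrane), ARFGEF3 (2.88 ± 0.20), UGT1A6 (2.82 ± 0.22) and SH2D5 (2.79 ± 0.30) were higher on silk. HP (-5.95 ± 0.52, a fitted value with about 2 reads in silk monocultures), A2M (-5.58 ± 0.48) and COL21A1 (-4.84 ± 0.36) were lower. Interferon response genes had 27 of 35 lower and 1 higher (the same over the list alone, median -0.81). For interferon response, camera gave adjusted p = 1.31e-09 (adjusted p = 0.365 with an estimated correlation). Mitochondrially encoded transcripts had 12 of 13 higher (12 over the list alone, median 0.98, camera adjusted p = 2.47e-05, adjusted p = 0.47 with an estimated correlation), and cholesterol synthesis genes 15 of 24 higher (16 over the list alone, median 0.50). For cholesterol synthesis, camera gave adjusted p = 2.47e-05 (adjusted p = 0.419 with an estimated correlation). Fibroblast markers had 29 of 32 lower and 1 higher (the same over the list alone, median -3.09). For fibroblast markers, camera gave adjusted p = 2.30e-17 (adjusted p = 0.197 with an estimated correlation). By limma, 5869 of 14433 genes were called, 2977 higher and 2892 lower on silk, and 14 of 37 lists by camera, 0 of them with an estimated correlation. Rescaling on epithelium-restricted genes moved the median of all genes by -0.27 and left 21.3% of the calls higher, against 50.7%.

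**Figure D2:**
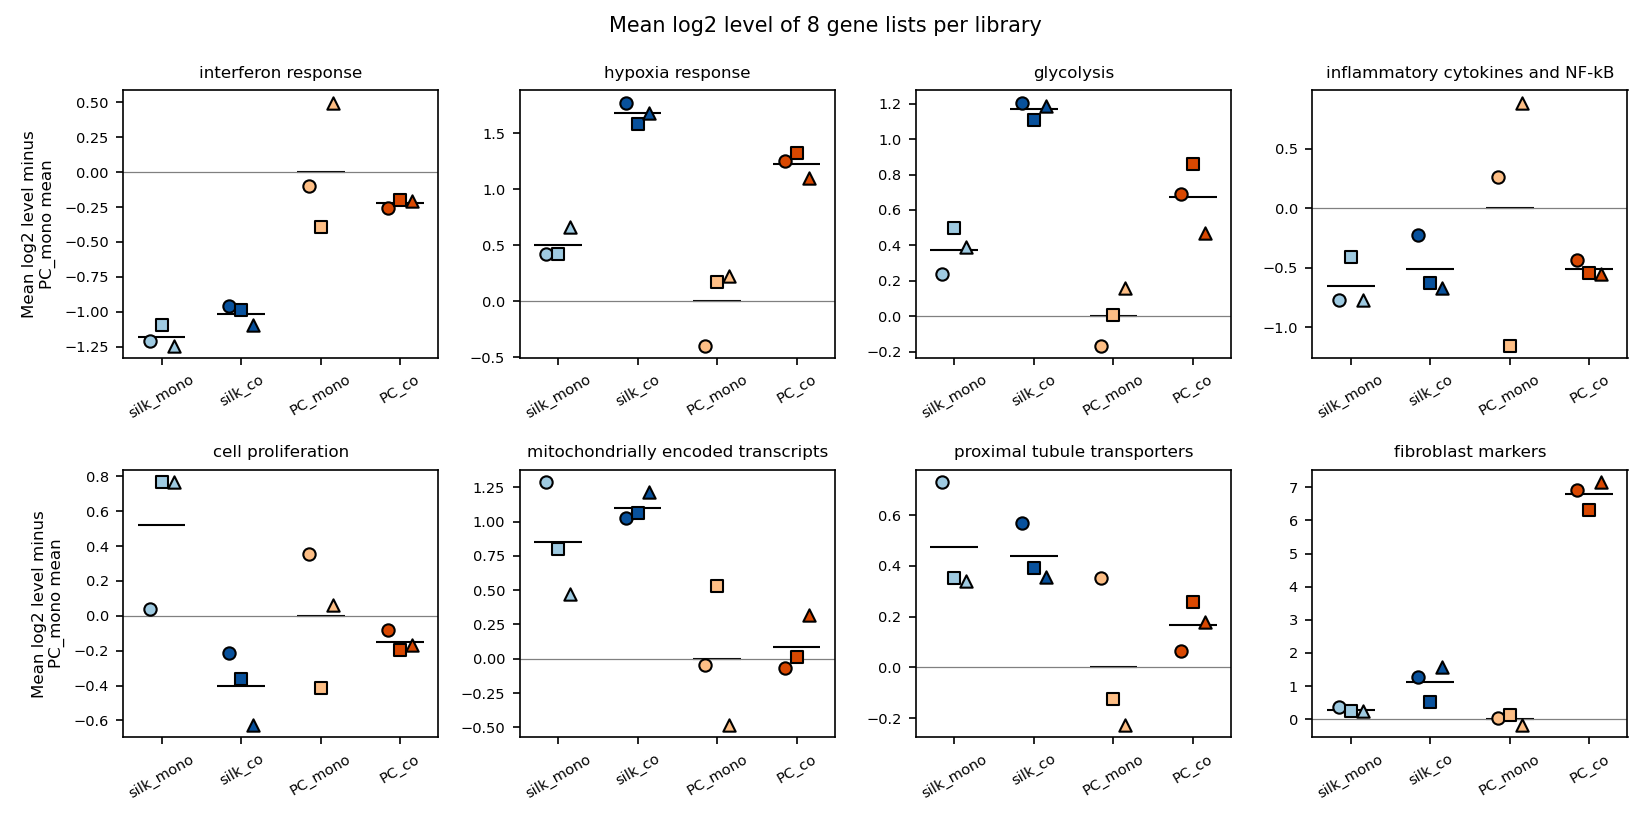
Mean log2 level of the genes of 8 lists in each of 12 libraries, relative to the mean of the LN/PC monoculture libraries, with 1 symbol per replicate and a line at the group mean. Interferon response genes lie lower in all silk libraries than in all LN/PC libraries, and hypoxia response genes lie higher in the co-cultures than in the monocultures of the same membrane.

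Silk co-cultures and silk monocultures were compared to ask what the addition of fibroblasts changed on silk, where fibroblast RNA was 0.0457% of the co-culture. HSPA6 was at 0 in all silk monoculture libraries and at 385, 929 and 151 in the silk co-culture libraries, at least 174-fold higher. MME, which encodes the membrane peptidase neprilysin, was higher by 3.44 ± 0.52 log2 units (SE, n = 3 per group, 111 ± 46.2 against 9.41 ± 5.13 normalized counts, SD). Fibroblast monocultures expressed MME at 8081 to 9024 and LN/PC co-cultures at 3543 to 7289, so its rise on silk need not be epithelial. The glucose transporter gene SLC2A3 was higher by 3.25 ± 0.24, the kinase gene SIK1 by 3.19 ± 0.31 and PTGES, the prostaglandin E synthase gene, by 3.15 ± 0.30. TXNIP (927 ± 251 against 4070 ± 747, -2.16 ± 0.24), the phosphate transporter gene SLC34A2 (-1.84 ± 0.43), the ribonucleotide reductase gene RRM2 (-1.82 ± 0.39), CHD9NB (-1.65 ± 0.38) and PIMREG (-1.63 ± 0.43) were lower.

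Hypoxia response genes rose in silk co-cultures, with 12 of 25 higher and 0 lower (19 higher over the list alone) and a median of 1.04. For hypoxia response, camera gave adjusted p = 9.44e-21 (adjusted p = 0.0658 with an estimated correlation). STC2 averaged 1527 ± 165 in silk co-cultures and 182 ± 5.61 in silk monocultures (3.06 ± 0.25), and NDRG1 (2.40 ± 0.25), ANGPTL4 (2.26 ± 0.39) and ERO1A (2.23 ± 0.17) were higher with it. Glycolysis genes had 4 of 22 higher and 0 lower (7 over the list alone), with HK2 (2.42 ± 0.19) and SLC2A1 (17943 ± 2528 against 3879 ± 179, 2.20 ± 0.19) and a median of 0.49. For glycolysis, camera gave adjusted p = 8.14e-11 (adjusted p = 0.192 with an estimated correlation). Of 25 unfolded protein response genes, 14 were higher and 1 lower (18 and 4 over the list alone), including ATF3 (2.49 ± 0.43), HSPA5 (25794 ± 1422 against 8291 ± 1110, 1.64 ± 0.22) and DDIT3 (1.61 ± 0.29), with a median of 0.71. For unfolded protein response, camera gave adjusted p = 2.25e-11 (adjusted p = 0.0988 with an estimated correlation). Cell proliferation genes fell, with 12 of 37 lower and 0 higher (30 lower over the list alone), including CDK1 (-1.53 ± 0.36), MKI67 (-1.45 ± 0.31) and KIF20A (-1.44 ± 0.28), and a median of -0.90. For cell proliferation, camera gave adjusted p = 9.44e-21 (adjusted p = 0.192 with an estimated correlation). Heat shock genes had 4 of 14 higher and 0 lower (4 over the list alone, median -0.04, camera adjusted p = 0.085), with CRYAB (2.13 ± 0.37) and HSPA1A (1.53 ± 0.20), which may share reads with HSPA1B.

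Growth factor targets had 6 of 24 higher and 0 lower in silk co-cultures (10 higher and 1 lower over the list alone, median 0.30), with IGFBP3 (2.39 ± 0.17). For growth factor signalling targets, camera gave adjusted p = 6.56e-05 (adjusted p = 0.155 with an estimated correlation). Immediate early genes had 4 of 22 higher (6 over the list alone, median 0.62), with KLF4 (2.82 ± 0.35) and KLF6 (1.43 ± 0.21). For immediate early genes, camera gave adjusted p = 0.000238 (adjusted p = 0.478 with an estimated correlation), and single libraries of the 2 groups overlapped by list mean. YAP and TEAD targets had 4 of 23 higher (7 over the list alone, median 0.33). For YAP and TEAD targets, camera gave adjusted p = 0.000796 (adjusted p = 0.258 with an estimated correlation). Fibroblast markers had 6 of 32 higher and 0 lower (9 higher and 1 lower over the list alone, median 0.34, or 0.17 with genes at 0 set to their bound). For fibroblast markers, camera gave adjusted p = 6.56e-05 (adjusted p = 0.4 with an estimated correlation). GREM1, a BMP antagonist gene, averaged 142 ± 15.8 in silk co-cultures and 17.2 ± 8.18 in silk monocultures (3.10 ± 0.41), PDGFRA was higher by 2.32 ± 0.58, and COL3A1 (27.9 ± 24.3) and the metalloproteinase inhibitor gene TIMP3 (28.5 ± 27.4), both at 0 in silk monocultures, were at least 9.98-fold and 10.2-fold higher. These bounds hold for the means only. Silk co-cultures 1 to 3 stood at 44.3, 0 and 39.6 for COL3A1 and at 28.9, 0.918 and 55.6 for TIMP3. Primary cilium genes (0 of 36 called, 0 over the list alone, median -0.23, camera adjusted p = 7.73e-05, adjusted p = 0.248 with an estimated correlation), histones (0 of 8, 0 over the list alone, median 0.74, camera adjusted p = 0.0189, adjusted p = 0.478 with an estimated correlation) and gluconeogenesis genes (0 of 15, 0 over the list alone, median -0.28, camera adjusted p = 0.0269, adjusted p = 0.192 with an estimated correlation) were called as lists without a called member. ABCB1 (log2 -0.62 ± 0.26), CUBN (-0.64 ± 0.62), HAVCR1 (-0.28 ± 0.52), AQP1 (0.10 ± 0.55) and COL1A1 (2.02 ± 0.91) were not called.

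By limma, 545 of 14433 genes were called between silk co-cultures and silk monocultures, 420 higher and 125 lower, of which 226 and 74 by at least 2-fold, and 65 of the higher genes were fibroblast-enriched. With upper-quartile scaling 66.1% of the calls were higher and with epithelium-restricted scaling 87.7%, against 77.1%. By camera 11 of 37 lists were called, and 0 with an estimated correlation. The count was 819 without LN/PC monoculture 2, 308 without silk monoculture 2, 342 without silk monoculture 3, 311 without silk co-culture 1, 321 without silk co-culture 2 and 207 without silk co-culture 3, and 1174 with the 6 compared libraries alone in the fit. Single left-out libraries (any of the silk monocultures, silk co-cultures and LN/PC co-cultures, and LN/PC monoculture 1) ended the calls of SLC34A2, RRM2, CHD9NB, PIMREG, CDK1, MKI67, COL3A1, PDGFRA and TIMP3 (adjusted p up to 0.257), ABCB1 was called without LN/PC monoculture 2 (adjusted p = 0.0274), and the gluconeogenesis list was not called without silk monoculture 2 (adjusted p = 0.0666).

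LN/PC co-cultures and monocultures were compared to ask the same question on LN/PC, where fibroblast RNA was 13.0% of the co-culture. Collagen genes were among those that rose. COL1A2 and COL3A1, at 0 in all LN/PC monoculture libraries, averaged 27708 ± 6252 and 27660 ± 10801 normalized counts (SD, n = 3) in LN/PC co-cultures, at least 9705-fold and 9688-fold higher, and COL6A3 (13.71 ± 1.097 log2 units, SE) and COL1A1 (11.50 ± 0.91) rose with them. TIMP3, with about 1 read over the LN/PC monoculture libraries, was 21943-fold higher (95% exact interval 3938 to 8.67e+05). The cytokine gene LTB (20.5 ± 2.07 against 369 ± 327, -3.36 ± 0.83), BMF (-2.38 ± 0.48), which encodes a pro-apoptotic protein, SH3RF2 (-2.28 ± 0.28), the laminin gene LAMB3 (-2.03 ± 0.43) and PAPLN (280 ± 79.0 against 1093 ± 135, -1.99 ± 0.20) were lower. The 552 epithelium-restricted genes had a median of -0.44 in this comparison, against -0.06 for the same comparison on silk.

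Fibroblast markers had 29 of 32 higher and 0 lower in LN/PC co-cultures (29 over the list alone), with a median of 7.60, or 6.98 with genes at 0 set to their bound. For fibroblast markers, camera gave adjusted p = 1.20e-47 (adjusted p = 0.00861 with an estimated correlation). Contractile genes had 12 of 17 higher (12 over the list alone, median 2.13), with TAGLN (6.23 ± 0.49) and MYL9 (5.97 ± 0.69). For myofibroblast and contractile genes, camera gave adjusted p = 1.35e-12 (adjusted p = 0.0563 with an estimated correlation). Metalloproteinases and inhibitors had 10 of 22 higher and 1 lower (11 and 5 over the list alone, median 0.33, camera adjusted p = 0.000853, adjusted p = 0.101 with an estimated correlation), TGF-beta response genes 8 of 26 higher and 4 lower (the same over the list alone, median 0.09). For TGF-beta response, camera gave adjusted p = 0.0104 (adjusted p = 0.101 with an estimated correlation). Ribosomal protein genes had 18 of 36 higher and 0 lower (25 over the list alone, median 0.57), with RPL27 (1.04 ± 0.18) and RPS29 (0.98 ± 0.22). For ribosomal proteins, camera gave adjusted p = 1.35e-12 (adjusted p = 0.317 with an estimated correlation). These 5 groups moved alongside the fibroblast RNA of 13.0%. AQP1, which fibroblasts expressed, rose by 3.40 ± 0.55, from 10.3 ± 4.38 to 121 ± 59.2.

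Hypoxia response genes rose in LN/PC co-cultures too, with 15 of 25 higher and 0 lower (17 and 1 over the list alone) and a median of 0.86. For hypoxia response, camera gave adjusted p = 1.97e-11 (adjusted p = 0.101 with an estimated correlation). ANGPTL4 rose by 4.17 ± 0.39 (643 ± 79.3 against 38.8 ± 23.9), CA12 by 3.58 ± 0.26, CA9 by 3.38 ± 0.91 and STC2 by 2.77 ± 0.25 (353 ± 56.7 against 53.7 ± 21.1). Glycolysis genes had 5 of 22 higher and 0 lower (10 and 2 over the list alone, median 0.37), with ALDOC (5.64 ± 0.43) and SLC2A3 (2.70 ± 0.24). For glycolysis, camera gave adjusted p = 0.000853 (adjusted p = 0.442 with an estimated correlation). Immediate early genes had 7 of 22 higher (9 over the list alone, median 0.85), with NR4A1 (5.55 ± 0.85) and FOSB (434 ± 83.5 against 25.6 ± 32.8, 5.44 ± 0.97). For immediate early genes, camera gave adjusted p = 0.000255 (adjusted p = 0.442 with an estimated correlation). Metallothioneins had 3 of 6 higher (3 over the list alone, median 0.83), with MT1X (1.16 ± 0.22), whose reads may be shared with other MT1 genes. For metallothioneins, camera gave adjusted p = 0.00632 (adjusted p = 0.442 with an estimated correlation). Epithelial groups were lower, alongside the median of -0.44 of the epithelium-restricted genes. Tight junction genes had 10 of 32 lower and 0 higher (11 lower over the list alone), including CLDN1 (-1.44 ± 0.27) and PARD6B (-1.06 ± 0.21), with a median of -0.39 that became 0.03 when rescaled on epithelium-restricted genes. For tight junction and polarity, camera gave adjusted p = 1.95e-06 (adjusted p = 0.127 with an estimated correlation). Nephron transcription factors had 5 of 22 lower and 1 higher (11 and 1 over the list alone, median -0.48), including LHX1 (-1.49 ± 0.38) and PAX8 (-0.99 ± 0.18). Their median was close to the -0.44 of the epithelium-restricted genes, so it need not reflect this list. For nephron epithelial transcription factors, camera gave adjusted p = 0.0023 (adjusted p = 0.148 with an estimated correlation). Drug metabolism genes had 8 of 22 lower and 2 higher (the same over the list alone, median -0.30, or 0.14 so rescaled), with UGT1A6 (-2.61 ± 0.31) and EPHX2 (-1.53 ± 0.39) (camera adjusted p = 0.0128, adjusted p = 0.243 with an estimated correlation), and NRF2 and heme stress genes 4 of 18 lower (5 over the list alone, median -0.27, or 0.16 so rescaled). For NRF2 and heme stress, camera gave adjusted p = 0.0128 (adjusted p = 0.442 with an estimated correlation). Inflammatory and NF-kB genes had 7 of 28 lower and 1 higher (10 and 3 over the list alone, median -0.93), with SOD2 (-2.00 ± 0.49) and ICAM1 (-1.98 ± 0.43). For inflammatory cytokines and NF-kB, camera gave adjusted p = 0.00843 (adjusted p = 0.73 with an estimated correlation). LN/PC monoculture 2, with a list mean of -1.16, lay below every LN/PC co-culture (-0.43, -0.54 and -0.56), and LN/PC monocultures 1 and 3 above them (0.27 and 0.89).

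By limma, 1807 of 14433 genes were called between LN/PC co-cultures and LN/PC monocultures, 1126 higher and 681 lower, of which 765 and 215 by at least 2-fold, and 651 of the higher genes were fibroblast-enriched. Rescaling on epithelium-restricted genes moved the median of all genes by 0.44, gave 4215 calls and made 96.8% of them higher, against 62.3%. By camera 14 of 37 lists were called, and 1 with an estimated correlation. The count was 753 without LN/PC co-culture 1, 1149 without LN/PC co-culture 3, 1133 without LN/PC monoculture 1 and 1088 with the 6 compared libraries alone. Single left-out libraries (any LN/PC co-culture, and LN/PC monocultures 1 and 3) ended the calls of LTB, LHX1, EPHX2, SOD2 and CA9 (adjusted p up to 0.0826), CA9 being at 0 in LN/PC monoculture 1 (log2 1.77 without it), and of the inflammatory list (without LN/PC monoculture 3, median -0.41, adjusted p = 0.425) and drug metabolism list (without LN/PC monoculture 2, adjusted p = 0.0627). Without LN/PC monoculture 2, ABCB1 (-0.89, adjusted p = 0.00215) and HAVCR1 (-1.70, adjusted p = 0.000262) were called, while with all libraries ABCB1 (-0.48 ± 0.26), HAVCR1 (-0.77 ± 0.52) and CUBN (-0.96 ± 0.62) were not.

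**Figure D3:**
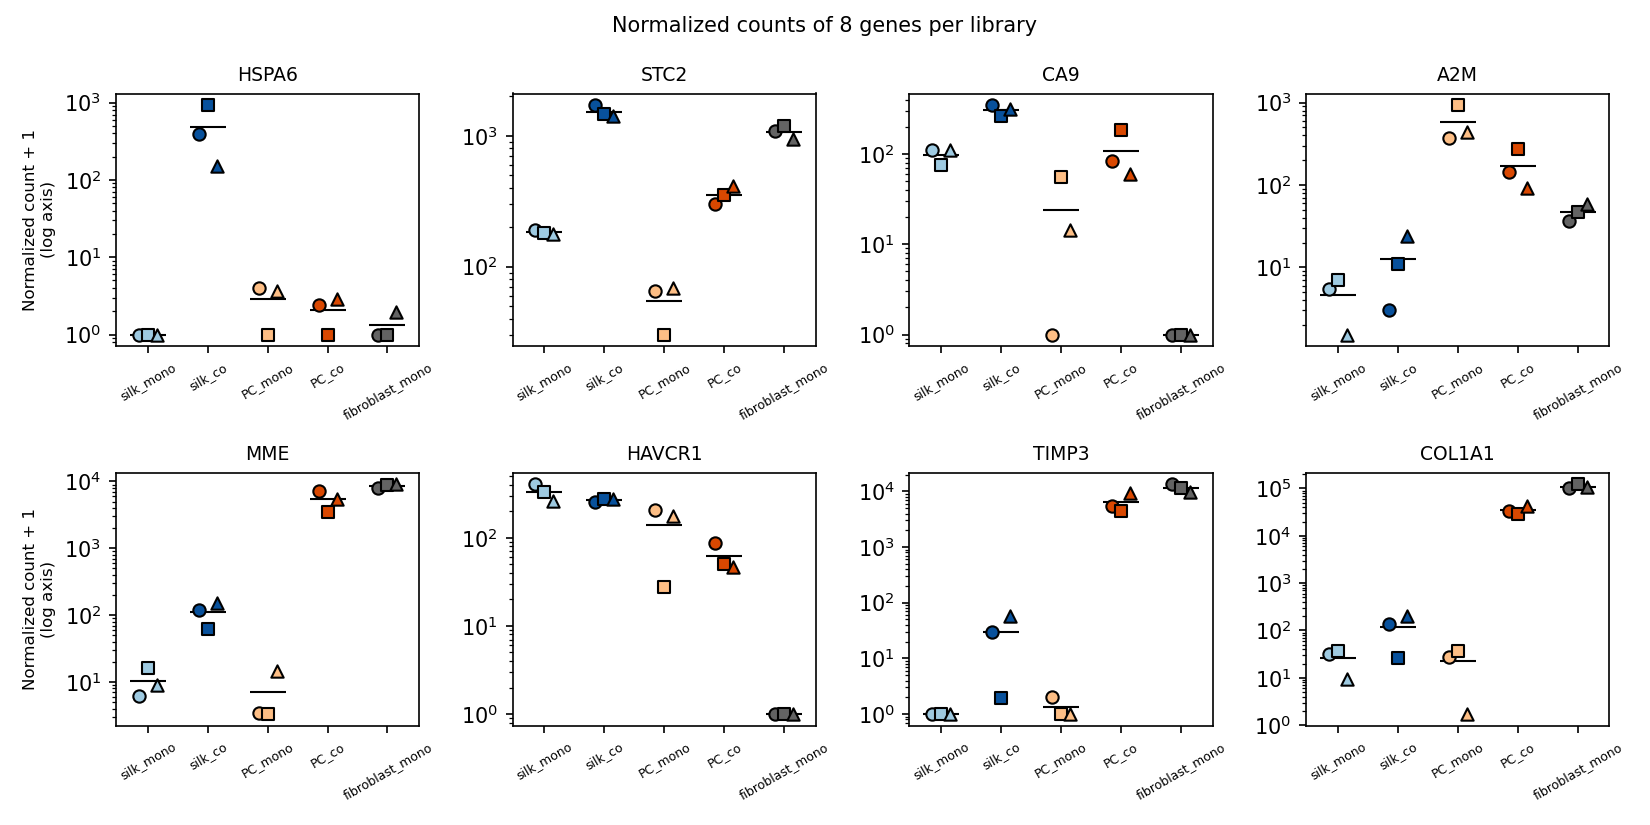
Normalized counts of 8 genes in each of 15 libraries, with 1 added and on a log axis, with 1 symbol per replicate and a line at the group mean. HSPA6 stands at 151 to 929 in the silk co-culture libraries and at 0 in the silk monoculture libraries, and COL1A1 is highest in fibroblast monocultures and LN/PC co-cultures.

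The interaction between membrane and co-culture tested whether the effect of added fibroblasts differed between membranes. Values here are the co-culture effect on silk minus that on LN/PC. They were positive for HSPA6 (8.94 ± 0.99 log2 units, SE, 12 libraries), KMO (3.88 ± 0.49), a kynurenine pathway gene, UPP1 (3.55 ± 0.32), which encodes uridine phosphorylase, and the carboxypeptidase gene CPA4 (2.98 ± 0.52). KMO went from 132 ± 41.2 to 700 ± 121 normalized counts on silk (SD, n = 3) and from 259 ± 94.4 to 99.98 ± 57.5 on LN/PC. The HSPA6 term, with silk monocultures at 0, depends on the pseudocount (12.41 with 0.1 and 5.39 with 10) and is no bound, and the terms of COL3A1 and COL1A2, at 0 in LN/PC monocultures, depend on it too. Values were negative for the fibroblast genes COL3A1 (-11.07 ± 1.36), COL1A2 (-10.81 ± 1.58), PDGFRB (-10.44 ± 0.86) and THBS2 (-10.21 ± 0.86). The terms of PDGFRB (-13.6 with a pseudocount of 0.1 and -6.3 with 10) and THBS2 (-12.8 and -7.1) depend on the pseudocount as well. Of 32 fibroblast markers 26 had a negative term (26 negative and 1 positive over the list alone, median -7.23, camera adjusted p = 5.07e-37, adjusted p = 0.0201 with an estimated correlation), and of 17 contractile genes 11 (12 negative and 1 positive over the list alone, median -1.95). For myofibroblast and contractile genes, camera gave adjusted p = 4.82e-10 (adjusted p = 0.105 with an estimated correlation). Ribosomal protein genes (4 of 36 negative, 8 over the list alone, median -0.51, camera adjusted p = 1.54e-06, adjusted p = 0.634 with an estimated correlation) and cell proliferation genes (3 of 37 negative, 3 over the list alone, median -0.78, camera adjusted p = 2.21e-06, adjusted p = 0.634 with an estimated correlation) also had a more negative co-culture effect on silk. Tight junction genes (6 of 32 positive, 8 positive and 1 negative over the list alone, median 0.43, camera adjusted p = 0.000193, adjusted p = 0.345 with an estimated correlation) and unfolded protein response genes (7 of 25 positive and 2 negative, 9 and 2 over the list alone, median 0.55, camera adjusted p = 0.00784, adjusted p = 0.519 with an estimated correlation) had a more positive effect there. The 552 epithelium-restricted genes had a median of 0.39 in the interaction, and rescaled on them the tight junction median was 0.07 and that of the unfolded protein response 0.18. The hypoxia response list was not called by this test (3 of 25 positive and 3 negative, the same over the list alone, median 0.04, camera adjusted p = 0.995).

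By limma, 1116 of 14433 genes were called in the interaction, 454 with a positive and 662 with a negative term. By camera 14 of 37 lists were called, and 1 with an estimated correlation. The count was 465 without LN/PC co-culture 1, 633 without LN/PC co-culture 3 and 725 without silk co-culture 3. Rescaling on epithelium-restricted genes moved the median of all genes by -0.36 and left 11.7% of the calls positive, against 40.7%. Across genes, the co-culture effects on silk and on LN/PC had a Pearson correlation of 0.217 and a Spearman correlation of 0.113, and 91 genes were higher in both (32.8 by independent lists) and 19 lower in both (5.90 by independent lists), while 23 were higher on silk and lower on LN/PC and 4 the reverse. Without the fibroblast-enriched genes the correlations were 0.0983 and 0.0767.

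Each co-culture was also compared with in-silico mixtures of its monoculture and fibroblast libraries, to separate genes that only follow the admixed RNA from others. On silk, where the mixture held 0.0457% fibroblast RNA, HSPA6, at 0 in all silk monocultures, SLC2A3 (3.25 ± 0.23 log2 units, SE, n = 3 per group), SIK1 (3.19 ± 0.29) and PTGES (3.15 ± 0.29) lay above the mixture, and TXNIP (-2.16 ± 0.22), SLC34A2 (-1.84 ± 0.42), RRM2 (-1.82 ± 0.37) and CHD9NB (-1.65 ± 0.36) below it. On LN/PC, at 13.0%, the immediate early genes FOSB (5.51 ± 0.91) and NR4A1 (3.78 ± 0.55), the sulfatase gene SULF1 (4.64 ± 0.54, 649 ± 102 normalized counts in LN/PC co-cultures against 192 ± 20.4 in fibroblasts) and RARRES2 (3.67 ± 0.43) lay above the mixture. Of 112 markers, 22 lay over 2 times and 25 under 0.5 times the mixture level. Among the genes below the mixture were ADH1B (-4.49 ± 0.69, 279 ± 234 in LN/PC co-cultures against 29290 ± 2786 in fibroblasts), EPHB6 (-3.95 ± 0.51), SVEP1 (-3.78 ± 0.49) and NPTX1 (-3.71 ± 0.47). By limma, 733 of 14517 genes were called on silk, 530 higher and 203 lower, and 630 on LN/PC, 285 higher and 345 lower. With upper-quartile scaling 61.7% of the calls on silk were higher, against 72.3%, and with trimmed-mean scaling 59.1% on LN/PC, against 45.2%. With the summed marker share in place of the median share, 713 genes were called on LN/PC, 226 higher and 487 lower (31.7% higher). Against the LN/PC mixture the 552 epithelium-restricted genes had a median of -0.24, with quartiles of -0.51 and 0.02. Against the silk mixture their median was -0.06. Genes called below the LN/PC mixture may therefore in part still follow admixed RNA. On silk the count was 422 without silk monoculture 2, 449 without silk monoculture 3, 459 without silk co-culture 1, 430 without silk co-culture 2 and 322 without silk co-culture 3, and on LN/PC 185 without LN/PC monoculture 1 and 229 without LN/PC co-culture 1. Leaving out silk co-culture 2 or 3, or the mixture made from silk monoculture 1 or 2, ended the calls of SLC34A2, RRM2 or CHD9NB on silk (adjusted p up to 0.0727).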

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

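The tests of a wrong label, of the marker ratio, of harvest and of scaling on epithelium-restricted genes were chosen after the results were seen, as were the bounds for the planned tests with mixtures, left-out libraries and 2 other scalings. The effect of added fibroblasts differed between membranes in 1116 genes by the limma interaction test, and 57 of the 127 genes named in the report were among them, 26 with a positive and 31 with a negative term. Values are log2 interaction terms, the co-culture effect on silk minus that on LN/PC, and say nothing about the level on either membrane. For HSPA6, COL3A1, COL1A2, POSTN, LUM, TIMP3, SULF1, ADH1B and SVEP1, each at 0 in at least 1 group, they are fitted values that depend on the pseudocount (HSPA6 12.41 with 0.1 and 5.39 with 10) and are no bounds. The terms of PDGFRB (-13.6 with 0.1 and -6.3 with 10) and THBS2 (-12.8 and -7.1) depend on it too.

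Genes that fibroblasts expressed had negative terms: COL3A1 -11.07, COL1A2 -10.81, PDGFRB -10.44, THBS2 -10.21, COL6A3 -10.14, POSTN -10.12, COL1A1 -9.48, LUM -8.91, TIMP3 -8.34, SULF1 -7.69, ADH1B -6.95, TAGLN -6.76, MME -6.45, MYL9 -5.74, SVEP1 -4.03 and PDGFRA -4.04. Terms were also negative for the secreted factor and receptor genes GREM1 -5.02, NPR3 -3.75, RARRES2 -3.41 and IGFBP3 -1.19, the hypoxia and glycolysis genes ALDOC -4.29, CA12 -2.26 and ANGPTL4 -1.91, the immediate early gene NR4A1 -4.21, and AQP1 -3.31, XAF1 -1.83, CDK1 -1.70, TXNIP -1.35, MT1X -1.25, RPS29 -1.16 and RPL27 -0.97.

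Terms were positive for the stress genes HSPA6 8.94, HSPA1A 2.19, HMOX1 1.88, HSPA5 1.58 and DDIT3 1.4999. They were also positive for the glucose and hypoxia genes SLC2A1 2.78, HK2 2.55, NDRG1 1.59 and ERO1A 0.88, the metabolic genes KMO 3.88, UPP1 3.55, CPA4 2.98, UGT1A6 2.79 and PTGES 2.06, the inflammatory genes TNFAIP3 2.93 and ICAM1 2.54, and FZD10 3.30, SH2D5 2.55, SH3RF2 2.39, LAMB3 2.26, SIK1 2.17, RELN 1.96, CLDN1 1.68, PAPLN 1.52, ARFGEF3 1.47 and CLDN16 1.14.

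By list, camera called 14, of which 1 stayed called with an estimated correlation, fibroblast markers (adjusted p = 0.0201 with an estimated correlation). Negative interaction medians were those of fibroblast markers -7.23, myofibroblast and contractile genes -1.95, metallothioneins -0.81, cell proliferation -0.78, matrix metalloproteinases and inhibitors -0.54, ribosomal proteins -0.51, primary cilium -0.36 and TGF-beta response -0.31, where the co-culture effect was more negative on silk. Positive medians were inflammatory cytokines and NF-kB 0.87, interferon response 0.56, unfolded protein response 0.55, tight junction and polarity 0.43, NRF2 and heme stress 0.36 and nephron epithelial transcription factors 0.28. The 552 epithelium-restricted genes had a median of 0.39 in the same contrast, alongside the fibroblast RNA of 13.0% in LN/PC co-cultures, so the smaller positive medians need not reflect those lists. Rescaled on these genes, the 6 positive medians were 0.51, 0.19, 0.18, 0.07, 0.00 and -0.07 in the same order. Without LN/PC monoculture 3 the inflammatory (median 0.52, camera adjusted p = 0.314) and interferon lists (median 0.21, camera adjusted p = 0.468) were not called. By camera adjusted p, metallothioneins lost their call without LN/PC monoculture 3 (0.0987), silk monoculture 1 (0.0540) or LN/PC co-culture 3 (0.0523). Nephron transcription factors lost it without silk monoculture 3 (0.0562) or LN/PC monoculture 2 (0.0575). The metalloproteinase call ended without LN/PC co-culture 3 (median -0.30, 0.0701). The interferon call also ended without silk monoculture 1 (0.0690), silk co-culture 1 (0.0524) or LN/PC co-culture 3 (0.0537).

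The near absence of fibroblast RNA from the silk co-cultures is the first pattern weighed. A monoculture under a wrong label is argued against for single libraries. Over the genes called without the library in question, silk co-cultures 1 to 3 lay at 0.928, 0.900 and 1.05 of the way from monoculture to co-culture. Held-out silk monocultures lay at most at 0.273. Each position was set by the other silk co-cultures, so it cannot tell whether the whole group was mislabelled. The upper quartiles of the marker shares of silk co-cultures 1 to 3 (0.108%, 0.058% and 0.252%) were set without the other silk co-cultures. They exceeded those of held-out monocultures (at most 0.0281%). Scaling is argued against, since the lowest LN/PC co-culture had 37.8 times the ratio of fibroblast to epithelium-restricted RNA of the highest silk co-culture, a ratio that scaling leaves untouched. Fibroblasts left behind when silk membranes were scraped off might account for a share of 0.0457%, and so might fewer fibroblasts living on silk. These 2 cannot be told apart, since harvest differed with the membrane.

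Lower interferon response genes on silk are the second pattern. A single library is argued against by the median nearest 0 without 1 of the 6 libraries, -0.73. After the trend with GC content and length was removed, with 97.1% of genes covered, the median was -0.87 with 23 genes called lower. The way of harvest could lower the list on silk in both kinds of culture, where the co-culture median was -0.73, and so could the membrane itself. These cannot be told apart here.

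Higher hypoxia response genes in co-culture on both membranes are the third pattern. Admixed RNA with the profile of the fibroblast monocultures is argued against by medians of at least 0.86 against the mixture. The mixture does not cover fibroblasts that express other genes in co-culture, so RNA from such fibroblasts stays open. On silk the mixture held 0.0457% fibroblast RNA, so that test nearly repeats the comparison with silk monocultures. Over 3 other scalings the medians were at least 0.86. On LN/PC these scalings moved the median of all genes by 0.015, 0.00028 and 0.44, none of them downward, so they could not have lowered the list there. On silk they moved it by -2.67e-05, -0.058 and 0.080. The rise therefore does not hang on the choice among these scalings, and no more is concluded about scaling. A single library is argued against by medians of at least 0.59. No biological explanation was tested, and the cause stays open.

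The numbers of called genes were compared with those of other groupings of the same libraries. For each pairwise comparison among epithelial groups, 1 of 10 splits gave as many calls as the real one, which was the real split, and the others gave at most 1 gene. Against the mixtures it was also 1 of 10, with at most 1 gene on silk and 3 on LN/PC otherwise, and 10 splits are too few for a share under 0.05. The real grouping was 1 of 100 for the interaction (at most 820 otherwise), 1 of 100 for the membrane average (at most 3120) and 1 of 84 for fibroblasts against epithelial cells (at most 5858). For the interaction, other groupings mix libraries of different groups, which also breaks up the membrane and co-culture differences. The 1 of 100 therefore does not test the interaction apart from those differences, and no conclusion about it is drawn.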

How the results depend on the processing

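Of the 192 gene results and 73 list results rerun, none turned its direction by limma or camera, and other calls were not followed, although with scaling on epithelium-restricted genes list medians changed sign, between the co-cultures to -0.06 (tight junction), -0.14 (glycolysis) and -0.29 (growth factor targets) and in LN/PC co-cultures to 0.03 (tight junction), 0.14 (drug metabolism) and 0.16 (NRF2), and in the interaction to -0.07 (nephron transcription factors). Of 2434 values of named genes under 16 alternatives, 2383 kept their call, 50 lost it and 1 gained it, and with single libraries left out 2170 of 2295 kept it. Of 923 list values 892 kept their call, and 836 of 867 with a library left out, but 70 of 73 lost it with an estimated correlation. Camera compares a list with the other genes, so scalings that shift all genes of a library alike can hardly change its calls. Calls kept under them say little about scaling. Fits of the compared groups alone called 754 (silk against LN/PC monocultures), 1174 (silk co-culture against monoculture), 1088 (the same on LN/PC) and 1174 (silk mixture), and the cause was not tested. A log2 fold of at least 1, stricter by construction, left 770, 2506, 300 and 980 genes in the pairwise comparisons, 1694 in the membrane average, 5238 for fibroblasts and 368 and 330 against the mixtures. Lists called with an estimated correlation numbered 0, 0, 0 and 1 in the pairwise comparisons, 1 in the interaction, 0 in the average and 1 for fibroblasts. Fry called 3 (monocultures), 7 (silk co-culture), 8 (interaction) and 33 (fibroblasts), and the cause was not tested. Scaling on epithelium-restricted genes gave 4215 calls for LN/PC co-culture, and without fibroblast-enriched genes the agreement across genes was 0.586. With 1 library left out, which leaves fewer samples, counts ran from 695 to 3208 (monocultures), 3415 to 5732 (co-cultures), 207 to 819 (silk co-culture), 753 to 2007 (LN/PC co-culture), 465 to 1359 (interaction), 322 to 913 and 185 to 938 (mixtures, where leaving out a fibroblast library also removes the mixture made with it). Depth limits genes with few reads, whose ratios have wide intervals.

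With the replicate number as a block, counts were 1317, 4811, 443 and 1558 in the pairwise comparisons, 942 in the interaction, 5474 in the average, 8365 for fibroblasts and 600 and 509 against the mixtures. The block ended the calls of MT-CO1 between the monocultures (adjusted p = 0.0824) and PIMREG on silk (adjusted p = 0.0723) by limma and changed no other named call. Pairs with the same number had correlations of -0.254 to 0.189, and 3 libraries correlated best with their own number. Higher correlations lay between different numbers: silk monoculture 1 and LN/PC monoculture 2 (0.327), LN/PC monoculture 2 and LN/PC co-culture 3 (0.317), and silk monoculture 1 and LN/PC co-culture 3 (0.223). These libraries had the highest mitochondrially encoded percent of their groups (6.58%, 3.80% and 3.04%). A difference shared by libraries of unlike number is therefore not covered by the block.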

Other observations

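Of 29 distal nephron markers 7 were measured in the epithelial cells, 1 higher and 2 lower on silk in monoculture (camera adjusted p = 0.863). SLC12A1, the cotransporter gene of the thick ascending limb, averaged 5011 ± 1516 normalized counts (SD, n = 3) in silk monocultures and 10589 ± 120 in LN/PC monocultures, and was lower on silk (-1.13 ± 0.21 log2 units, SE, limma adjusted p = 0.00355). The potassium channel gene KCNJ1 was at 2911 ± 191 and 2271 ± 142 and was not called. SERPINA1 was at 5748 ± 2214 on silk and 44519 ± 8819 on LN/PC in monoculture (-3.02 ± 0.34, limma adjusted p = 5.61e-05).

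Some fibroblast-expressed genes stood out in the co-cultures. MME was at 5458 ± 1874 in LN/PC co-cultures and 8684 ± 524 in fibroblasts (SD, n = 3). NPTX1 was at 38.4 ± 8.59 in silk co-cultures, 0.805 ± 0.789 in silk monocultures and 1294 ± 119 in fibroblasts. ENG was at 583 ± 280 in LN/PC co-cultures and 1672 ± 212 in fibroblasts. The endothelial list had 2 members measured and the immune list 1, and neither was tested.

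The following test was chosen after the result was seen. Fibroblasts in co-culture might express other genes than those on the well bottom: 42.0% of the 112 marker genes lay outside 0.5 to 2 times the mixture level in LN/PC co-cultures, 22 above and 25 below. That share lay between the levels set for and against this hypothesis, so those levels did not decide it. A single share of an unchanged fibroblast profile would put all markers near 1 level. The quartiles of the marker shares were 6.67% and 22.7%, 4.32% and 15.1%, and 9.23% and 26.1% in LN/PC co-cultures 1 to 3. For these 112 genes the values argue against RNA of an unchanged profile at 1 share. Which cells changed was not tested.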
